A study of Drosophila melanogaster with 4 samples.

How the data were processed

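The series profiled the genomic binding of Ultraspiracle (USP) in Drosophila melanogaster embryos by chromatin immunoprecipitation and sequencing (ChIP-seq). USP is the fly member of the RXR family of nuclear receptors and the partner of the ecdysone receptor EcR. The strain carried a transgene of the USP genomic coding region fused to green fluorescent protein (GFP), and a rabbit polyclonal antibody against GFP pulled down the fusion protein, per the labels. Embryos were collected over 0 to 12 h and fixed in 1.8% formaldehyde for 15 min, per the labels' protocols. There were 2 ChIP libraries and 2 Input libraries of total chromatin DNA. The labels number the libraries of each kind as replicates but do not say whether they came from separate embryo collections. The labels' collection step names a y; bw cn sp stock, while the sample labels name the USP-GFP strain.

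The deposited data used here were 1 peak list. It gave the first and last base of each peak and a score per peak, with MACS named as the caller and FlyBase release 5 as the genome, per the file headers and columns. The submitters' processing notes name CASAVA 1.7.0.2, CASAVA 1.7.0.3, BWA, MACS2 and the build BDGP5, without settings. How the authors' peak score was defined (from a p-value, a q-value or another quantity) is not given in the sources used here, nor is which ChIP and Input libraries entered the peak calls or whether they were pooled. The score was therefore used only within this list, to describe, rank and filter its peaks and to compare them with each other (its correlation with width and differences of medians), and its size has no meaning outside it. Read counts per library are not known from this list, so sequencing depth is unknown, no value has a replicate error, and the agreement of the replicates was not analysed here.

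Peaks are described by their release 5 coordinates, counted from 1. The annotation at hand was a gene table of Release 6, another build, and coordinates of the 2 builds were not mixed. No gene was therefore assigned to a peak, and the planned tests of promoter share, feature classes, gene lists, sequence motifs and promoter peak scores were not run. The fixed gene lists covered ecdysone response, ecdysteroid synthesis, nuclear receptors, embryonic patterning, Hox, Notch, tissue markers and housekeeping groups, and none of them was tested. By the rule fixed before the data were examined, the items named are then the 20 peaks with the highest score, by position. The regions named besides these were those with the most peaks and those with peaks of score 100 or more, chosen after their values were seen.

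Comparisons ran on the 6 major arms (2L, 2R, 3L, 3R, 4 and X). The centre of a peak was its midpoint, since no summit was listed. Clustering was tested by counting neighbouring centres under 5 kb apart and comparing the count with 100000 random placements, uniform between the first and last centre of each arm (two-sided permutation p). The smallest p these placements can give is 2.00e-05. Score and width were compared across peaks by Spearman and Pearson correlation with permutation p from 100000 resamples, of which the smallest possible is 1.00e-05. Arm lengths of release 5 were not at hand, so the density of an arm was taken over the span from its first to its last peak. An exact two-sided binomial test of each arm's share against its share of the summed spans, with exact (Clopper-Pearson) 95% intervals and Benjamini-Hochberg adjustment over arms, was added after the data were seen. Peaks are not replicates and lie in clusters, so these p-values and intervals cover counting error only and are too small where peaks are not independent. Densities were therefore also compared between 1-Mb windows. Differences of medians were tested by two-sided permutation with 100000 resamples.

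Periodic spacing was tested in regions of 10 or more peaks. Peaks within 500 bp were merged first, regions were linked by centres under 20 kb apart, and the largest Rayleigh power over periods of 2 to 10 kb was compared with 100000 random placements in the same span. Alternatives were the peaks with scores above the median, merging within 500 bp, all sequences of the list and neighbour distances of 2 kb and 20 kb. Further alternatives, added after the data were seen, left out the densest region of 2L, left out the widest peak, merged within 2 kb or counted peaks under 5 kb apart once. Merged intervals cannot lie closer than the merging distance, so they were also compared with random placements that kept their widths and that smallest gap. The test of peaks with a score of 100 or more, its merged versions and the period test with this gap were likewise added after the data were seen.

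The scripts were tested on simulated data. For the 1397 arm peaks, the clustering test called 2 of 50 lists with no planted neighbours and 50 of 50 lists in which 10% of peaks had one. After merging within 500 bp, with the smallest gap kept, it likewise called 2 of 50 and 50 of 50. The binomial test called X in 0 of 50 lists without a difference and in 50 of 50 with X at 1.5 times the density. These lists gave each peak its arm independently, so they do not show how often the test calls clustered peaks falsely. With 300 simulated peaks, the score and width test called 1 of 20 lists with no correlation and 20 of 20 with a planted correlation of 0.3. The period test on 40 peaks called 3 of 100 random lists and 100 of 100 lists with a planted period. With the smallest gap kept, on lists of 31 peaks before merging, it called 3 of 50 and 50 of 50. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.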

Results

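Peaks of GFP-tagged USP in embryos of 0 to 12 h were examined as 1 list of 1540 non-overlapping intervals on 13 sequences of FlyBase release 5. The series holds 2 ChIP and 2 Input libraries, and which of them entered the peak calls is not given in the sources used here. The list carried no values per library, so no value has a replicate error. The 6 major arms held 1397 peaks (90.7% of the list), the unplaced sequences U and Uextra 124, 4 Het scaffolds of heterochromatic sequence 7, and the mitochondrial genome 12. Arm peaks covered 898 kb in all. Their median width was 386 bp (interquartile range 266 to 681 bp), with 197 peaks of 1 kb or more and 9 of 5 kb or more. The narrowest was 201 bp and neighbouring peaks were never closer than 50 bp. The authors' peak score had a median of 12.9 on the arms (interquartile range 10.0 to 19.5) and ran from 6.08 to 361.49.

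The first question was which sites had the highest peak scores for USP-GFP. The highest-scoring peak of the list lay on 2L at 15908166 to 15914119, with a score of 361.49 and a width of 5.95 kb. The next arm peaks were on 2L at 6073384 to 6082840 (score 348.57, 9.46 kb), on X at 1834460 to 1847262 (score 290.54, 12.8 kb), on 3L at 17955281 to 17987476 (score 273.37, 32.2 kb) and on 2R at 5434321 to 5437151 (score 247.54, 2.83 kb). Of the 20 highest scores, 6 were on 2R, 5 on 2L, 3 on 3L, 2 on 3R and 1 on X. The 17 arm peaks among these 20 were all at least 1506 bp wide. The other 3 were narrow peaks on unplaced sequences, at U 2605808 to 2606355 (score 361.18, 548 bp), Uextra 22939301 to 22939839 (score 307.12, 539 bp) and Uextra 13398658 to 13399060 (score 184.67, 403 bp).

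The remaining 12 of the 20 completed the set on the arms. On 2L they lay at 2196496 to 2203670 (score 205.03), 3338376 to 3342686 (score 186.9) and 8161359 to 8162864 (score 145.43). On 2R there were 3 nearby peaks, at 6106652 to 6109184 (score 178.85), 6097836 to 6100528 (score 169.29) and 6111882 to 6116316 (score 148.87), and a pair at 15157990 to 15161264 (score 186.09) and 15141506 to 15145482 (score 143.16). On 3L they lay at 18613098 to 18615169 (score 188.28) and 15133194 to 15135259 (score 165.96). On 3R a pair lay at 17439999 to 17444527 (score 167.22) and 17430790 to 17433163 (score 163.19).

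Arm peaks with a score of 100 or more, a bound chosen after the scores were seen, lay close to one another more often than randomly placed ones. These 31 peaks fell into 21 regions, linking all peaks with centres under 20 kb apart, and 8 of these regions held 18 of the 31. Among the 31, 7 neighbouring centres were under 20 kb apart, against a mean of 0.202 in 100000 random placements (SD 0.447, permutation p = 2.00e-05, the smallest the placements can give). Some of these neighbours were parts of one merged interval. With all peaks within 500 bp merged first, 28 intervals reached this score and 4 neighbours remained, against a mean of 0.0951 for random intervals with the same widths and smallest gap (permutation p = 2.00e-05), and after merging within 2 kb 3 remained among 27, against 0.0610 (permutation p = 8.00e-05). The random placements were uniform between the first and the last peak or interval of this score on each arm, not over the whole arm. Arm peaks of any score were themselves grouped (below). These tests therefore cannot tell whether high-scoring peaks were more grouped than other peaks, since sets of 31 drawn from the list were not compared. The 2R region from 6097836 to 6126750 held 4 peaks of score 100 or more among 11 peaks, and peaks covered 62.0% of its 28.9 kb. The 2L region from 6073384 to 6092660 held 2 among 8 peaks and was covered to 92.5%. On X, the region from 1834460 to 1889805 also held 2 among 8 peaks, with 47.9% of 55.3 kb covered.

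**Figure D1:**
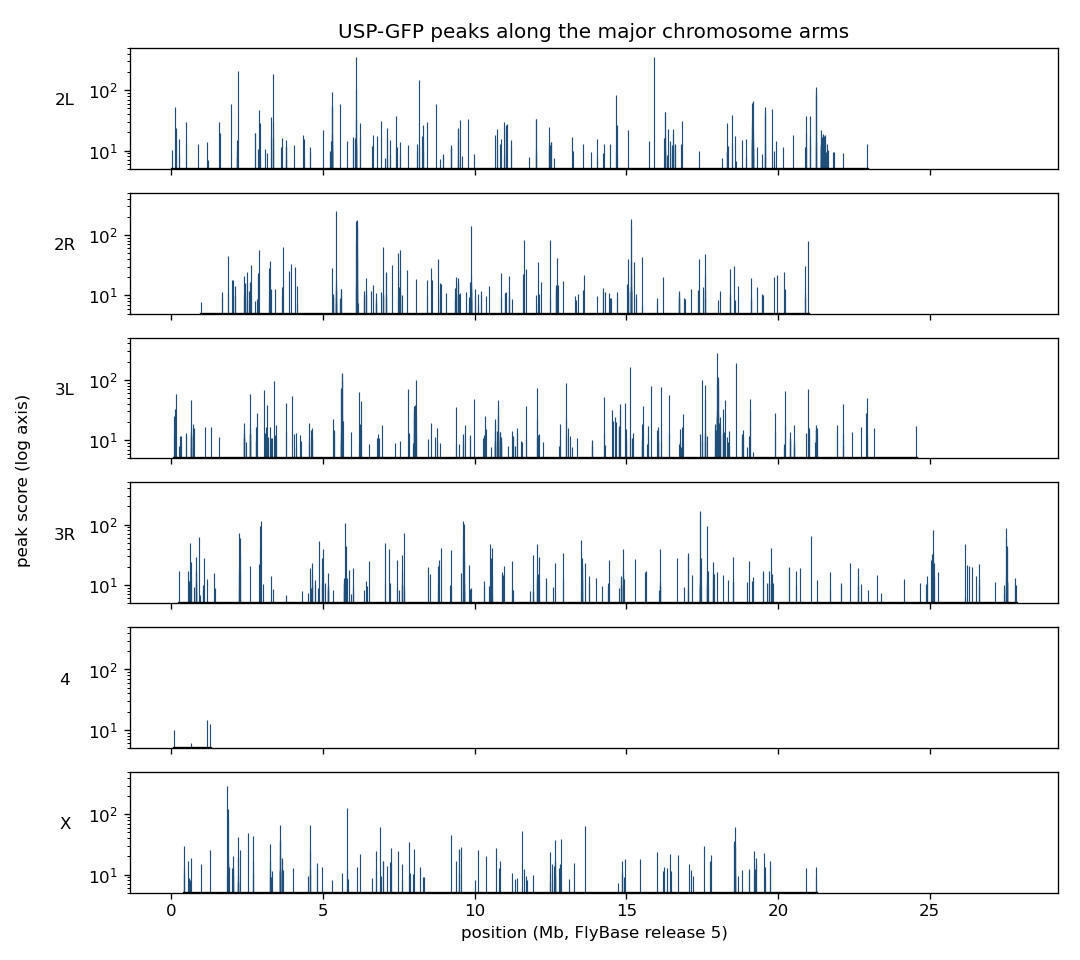
Each vertical line is 1 peak at its centre (x axis, position in Mb of FlyBase release 5) with its height at the authors' peak score (y axis, log scale), in 1 panel per major arm, and the black bar spans the first to the last peak. The highest lines stand on 2L (361.49 and 348.57), X (290.54) and 3L (273.37), and chromosome 4 has 4 low peaks.

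The same was seen over all arm peaks, which addressed whether USP-GFP peaks were spread singly or in groups. Of the 1397 arm peaks, 825 (59.1%) had another peak centre under 5 kb away. Neighbouring centres under 5 kb apart numbered 577, which was 6.97 times the mean of 82.7 in random placements (SD 8.56, largest 122, permutation p = 2.00e-05). Linked at this distance, the peaks formed 820 regions. Of these, 572 held a single peak, 210 held 2 to 4 and 38 held 5 or more, and the 38 regions carried 320 peaks. Many neighbours were separated by short gaps. After peaks within 500 bp were merged, 213 neighbours remained, 4.51 times the random mean of 47.2 (permutation p = 2.00e-05). After merging within 2 kb, 58 remained, 1.66 times the random mean of 35.0 (permutation p = 3.00e-04). Random placements of the merged intervals that kept the same smallest gap gave lower means, 35.1 and 14.3, and the ratios to these were 6.06 and 4.05 (permutation p = 2.00e-05 for both). All these placements were uniform along each arm and took no account of where genes or mappable sequence lie. The excess is therefore relative to uniform spacing only.

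The regions with the most peaks differed in their highest scores. On 3L, 28 peaks lay from 17952684 to 18031299 and covered 77.2% of its 78.6 kb; this region held the widest peak of the list, and its peak scores had a median of 19.5. Also on 3L, 17 peaks lay from 5601602 to 5649073, with a highest score of 130.77 and 57.2% of 47.5 kb covered. On 2L, 16 peaks lay from 19135854 to 19165253, with a highest score of 66.22. The next 3 regions held 12 peaks each, on 2R from 15136954 to 15163872 (highest score 186.09) and on 3R from 9615267 to 9647515 (114.84) and from 27511657 to 27551910 (88.98). The largest group lay on 2L from 21416791 to 21538580, where 59 peaks had scores of 6.68 to 21.47 (median 12.5) and covered 26.0% of 122 kb. Merged within 500 bp, its peaks recurred at a period of 4.98 kb (permutation p = 2.00e-05, or 1.00e-05 against random intervals that kept their widths and smallest gap). That group was 19.5% of all 2L peaks. Without it, the neighbours under 5 kb were 6.84 times the random mean.

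**Figure D2:**
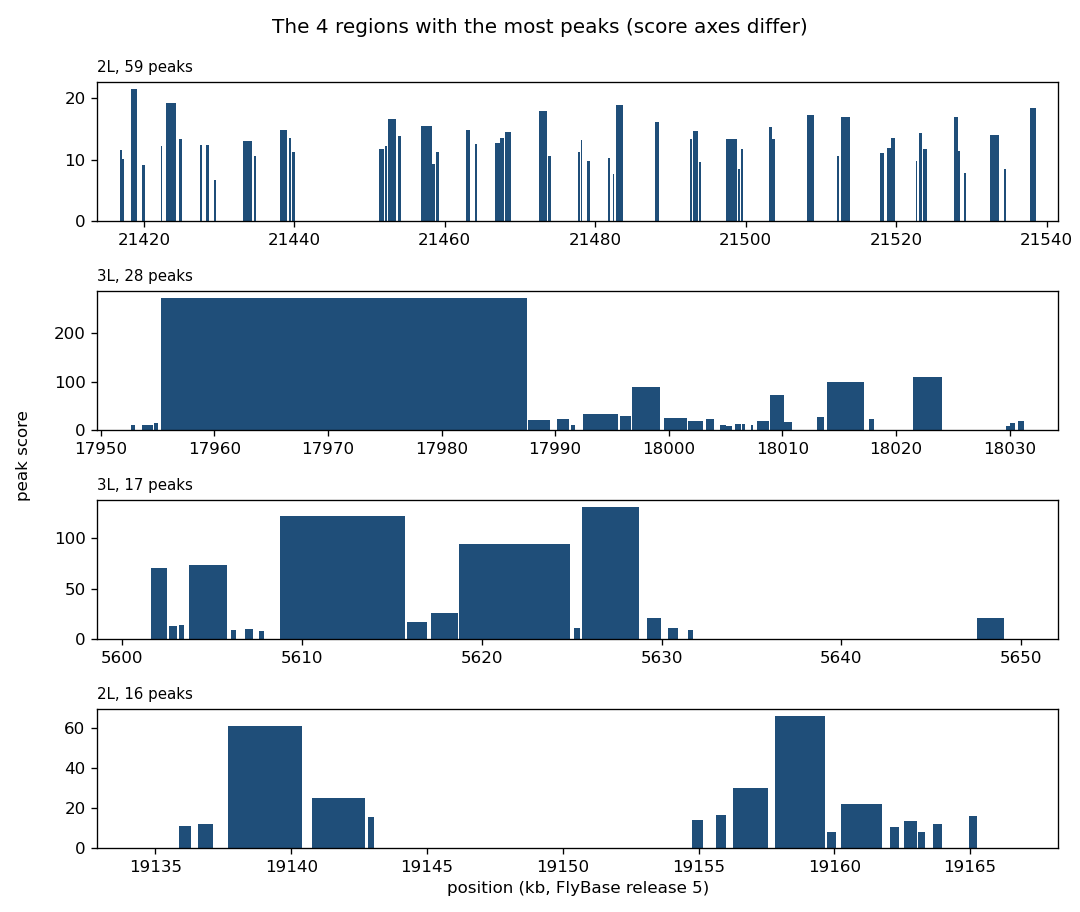
Peaks in the 4 regions with the most peaks (centres linked under 20 kb), drawn to scale along the x axis (kb, FlyBase release 5) with the bar height at the authors' peak score (y axis, linear, a separate scale per panel). The 59 peaks of the first 2L region score at most 21.47, while the 28 peaks of the first 3L region include 1 of 32.2 kb with a score of 273.37.

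Wider peaks had higher scores. Across the 1397 arm peaks, Spearman's rho between score and width was 0.76 (permutation p = 1.00e-05, the smallest possible) and Pearson's r was 0.72 (permutation p = 1.00e-05), or 0.83 without the 32.2 kb peak. Peaks are not independent replicates, and the relation describes this list. The 31 arm peaks of score 100 or more were 1222 bp to 32.2 kb wide, with a median of 2693 bp.

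Peak density differed between the arms, but none passed the test when clustered peaks were counted once. X had 177 peaks, 8.50 per Mb of the span from its first to its last peak, and chromosome 4 had 4, or 3.32 per Mb. The other arms had 14.4 per Mb (3L, 352 peaks), 13.2 (2L, 303 peaks), 12.9 (2R, 257 peaks) and 11.01 (3R, 304 peaks). X held 12.7% of arm peaks (exact 95% interval 10.97 to 14.5%) against 17.8% of the summed span, 0.712 times its share (exact binomial test, adjusted p = 1.28e-06). Chromosome 4 was at 0.278 times its share (exact binomial test, adjusted p = 0.00621) and 3L at 1.21 times (adjusted p = 3.06e-04), while 2L, 2R and 3R did not pass (adjusted p = 0.0757, 0.201 and 0.130). After peaks within 500 bp were merged, X was at 0.753 times its share (exact binomial test, adjusted p = 7.94e-04) and 3L at 1.18 times (adjusted p = 0.0121), while chromosome 4, at 0.367 times, no longer passed (adjusted p = 0.0632). With peaks under 5 kb apart counted once, X was at 0.829 times its share and 3L at 1.15 times, both with an exact binomial adjusted p = 0.0855, and chromosome 4 at 0.473 times (adjusted p = 0.325). In 1-Mb windows, X had 8.70 ± 5.54 peaks (SD, 20 windows) and the 4 large autosomal arms 12.9 ± 9.93 (SD, 92 windows), a difference of -4.23 that did not pass a permutation test (p = 0.0653). The medians were 6.5 and 10. The autosomal windows included a 2L window of 73 peaks that holds the densest 2L region, and the window test was not repeated without it. Scores on X, with a median of 13.4, stood beside a median of 12.7 on the large autosomal arms. Read depth and copy number per arm were not taken into account, so these densities describe called peaks and not numbers of binding sites.

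Outside the arms, unplaced sequences held a few narrow peaks of very high score and the median score of the mitochondrial peaks was above that of the arms. The 124 peaks on U and Uextra had a median score of 13.3 and a median width of 338 bp, against 12.9 and 386 bp on the arms, and neither difference passed (permutation adjusted p = 0.523 and 0.183 over 3 tests). Unplaced peaks of score 100 or more were 4 in number and 378 to 548 bp wide, all narrower than the narrowest arm peak of that score (1222 bp). The 12 mitochondrial peaks had a median score of 22.01, higher than the arm median by 9.15 (permutation adjusted p = 0.0419). They lay between positions 1484 and 19232 and covered 38.8% of that span, where arm peaks covered 0.768% of theirs. The 2 shares are not on a like footing, since the mitochondrial span is only 17.7 kb and arm spans are whole arms. Single arm regions with many peaks were covered more, such as 92.5% of the 19.3 kb on 2L from 6073384 to 6092660. Read depth on the mitochondrial genome was not known, so its scores and coverage do not show stronger binding. The permutation treated the 12 mitochondrial peaks as independent though they share 1 sequence, so its p-value is too small where they are not.

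**Figure D3:**
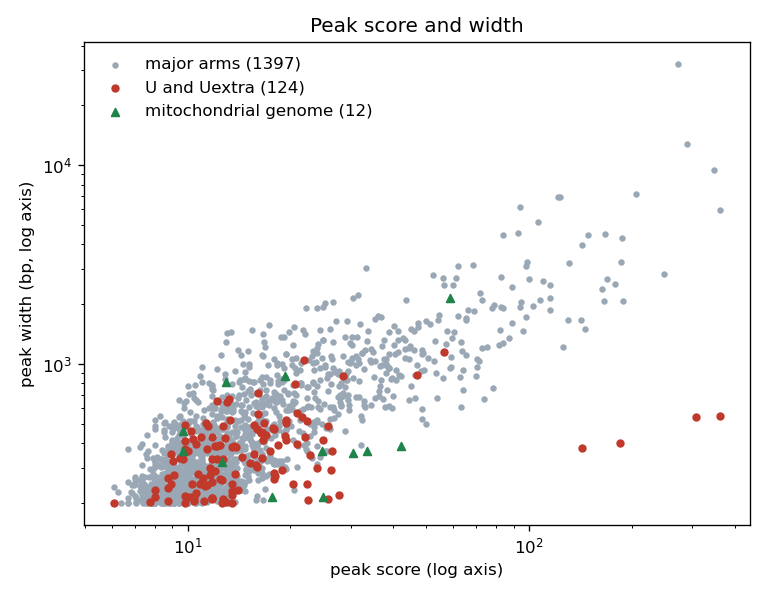
Each point is 1 peak, with the authors' peak score on the x axis and its width in bp on the y axis (both log scales), for the 1397 major-arm peaks (grey), 124 peaks on U and Uextra (red) and 12 mitochondrial peaks (green triangles). Arm peaks widen with score (Spearman's rho 0.76), while 4 unplaced peaks with scores of 142.4 to 361.18 are only 378 to 548 bp wide.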

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

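The tests in this part were chosen after the results were seen. Signal appeared on sequences that the comparisons of the major arms do not use. There were 124 peaks on the unplaced sequences, with a highest score of 361.18, 12 peaks on the mitochondrial genome and 7 on the Het scaffolds. The strongest mitochondrial peak lay at 12762 to 14899 with a score of 58.76. On U, 9 peaks from 5289960 to 5303434 had scores of 14.45 to 56.39. The highest score on the Het scaffolds was 29.94.

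Unplaced and mitochondrial peaks were narrow for their score, measured against the width that a log-log line through the arm peaks gives at the same score. The median of all 124 unplaced peaks was 0.829 times that of the arm peaks (permutation adjusted p = 3.00e-05 over 3 tests), and that of the 12 mitochondrial peaks was 0.698 times (adjusted p = 0.00716). The permutations treated peaks as independent, though the 12 mitochondrial peaks share 1 sequence. The 25 unplaced peaks of score 20 or more, which include the 4 that drew attention to the pattern, were at 0.528 times the 342 arm peaks of that range (permutation adjusted p = 3.00e-05). The set of 124 holds these 4 as well, so neither p-value for unplaced peaks is independent of the observation that prompted the tests. The 7 Het scaffold peaks, with a median score of 10.9 and a median width of 416 bp, were not tested. For the unplaced peaks, a candidate explanation is that short or repeated fragments limit the width. It stays open, since the fragment ends needed to decide were not used here. The widest unplaced peak, at 1157 bp, does not decide it. A peak can be narrow for its score through a reduced width or a raised score. The measure cannot tell these apart, for unplaced and mitochondrial peaks alike. No biological explanation was tested.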

How the results depend on the processing

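Of 41 values under alternatives, 37 kept their side of the threshold and no called value changed direction. The uncalled ratios of 2L (0.931 without its densest region) and 2R (0.897 among the higher-scoring peaks) crossed 1. The 4 values that did not keep their side were arm densities that lost their call. Chromosome 4 moved to an adjusted p of 0.0632 at 0.367 times its span share after merging peaks within 500 bp. With peaks under 5 kb apart counted once, an alternative chosen after seeing the data, chromosome 4 was at 0.473 times its share, 3L at 1.15 times and X at 0.829 times. That setting counts fewer, more independent items, so it has less power as well as less clustering. Among the higher-scoring peaks chromosome 4 had 1 peak, 0.139 times its share. The excess of neighbours was 12.7 times random under 2 kb and 2.58 times under 20 kb. It was 8.66 times among the peaks with scores above the median and 6.06 and 4.05 times after merging within 500 bp and 2 kb against random intervals with the same smallest gap. Against random centres without that gap it was 4.51 and 1.66 times, which understates the excess by construction. For peaks of score 100 or more, the 34.6-fold excess of neighbours was 42.1-fold and 49.2-fold after these 2 mergings, on 4 and 3 neighbours. The neighbours fell from 7 before merging, and the random means from 0.202 to 0.0951 and 0.0610. The rise in fold therefore does not show stronger grouping. With so few peaks placed at random, these folds cannot be compared with those of all arm peaks. The period of the dense 2L region still passed against random intervals with the same smallest gap. Spearman's rho of score and width ranged from 0.73 to 0.77 over its 5 alternatives. No paired analysis was possible because the peak list carries no values per library. For the same reason no library could be left out. Not run were all alternatives that need gene starts or sequence of release 5, those that need another value per peak, and arm shares over all sequences of the list. Unknown sequencing depth limits every count of peaks, since weaker sites can fall below the calling threshold.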

Other observations

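Apart from merging peaks within 500 bp, the tests in this part were chosen after the results were seen. The 59 peaks on 2L from 21416791 to 21538580 recurred at a partly regular spacing. Merged within 500 bp, they made 31 peaks, and their positions had a best period of 4.98 kb, with a mean phase vector of length 0.725 (on a scale where 1 is a perfect period). The period was not kept throughout. No peak lay between 21440030 and 21451258, and some periods held more than 1 merged peak. Random intervals that kept the widths and the smallest gap of 500 bp never gave as strong a period in 100000 placements (permutation p = 1.00e-05), and their longest vector was 0.686. It was the single region with 10 or more merged peaks, so no other region was tested. Such a spacing could come from reads of a tandemly repeated sequence, with 24.4 periods in the span. Whether USP-GFP was bound in each copy (period 4.98 kb under either reading) or reads merely piled up on repeats cannot be told apart, since positions alone carry no sequence and no read depth. The median score of these peaks, 12.5, was close to the 12.9 of all other arm peaks (difference -0.405, permutation p = 0.637), but their interquartile range was narrower, 10.9 to 14.5 against 10.0 to 20.4.

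The grouping of peaks on the arms had candidate technical explanations. The caller's splitting of single enriched regions, at gaps of 500 bp or less, is argued against as the whole cause. The neighbours were still 4.51 times random after merging within 500 bp, and 6.06 times when random intervals kept the same smallest gap. The dense 2L region is argued against too, since without it the ratio was 6.84. After merging within 2 kb the neighbours were 4.05 times random intervals with the same smallest gap. In counts, they fell from 577 to 213 after merging within 500 bp and to 58 within 2 kb. The random means fell too, from 82.7 to 35.1 and 14.3 with the gap kept, which held the ratios up. Most of the excess in counts thus went with merging, which joins split pieces and separate close peaks alike. How much of the excess splitting accounts for therefore stays open. A biological explanation, several USP-GFP sites in one regulatory region, was not tested, because sequence and gene positions of release 5 were not used here. For the same reason, an uneven spread of genes or mappable sequence along the arms, which uniform placements ignore, was not examined.

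Among the 70 highest-scoring arm peaks, 50 (71.4%) had a neighbouring centre under 5 kb away, against 775 of the other 1327 (58.4%). Fisher's exact test gave p = 0.0338 and an adjusted p of 0.0676 over 2 tests, so the difference fails the correction. The median score was 12.6 with such a neighbour (825 peaks) and 13.0 without (572 peaks), and a permutation test did not separate them (adjusted p = 0.406). Distances between centres leave wide peaks without a neighbour even where another peak lies near their edge. The 3L peak ending at 17987476 (32.2 kb, score 273.37) was counted so, though the next region started at 17987637. Wider peaks had higher scores, so both comparisons hold for centre distances only. Distances between edges were not compared.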
